A study of Lynx rufus with 52 samples.

How the data were processed

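Whole blood of bobcats (Lynx rufus) was profiled by RNA sequencing in 52 samples. Anticoagulant rodenticides had been detected in 26 samples and not in the other 26, per the labels, which set the groups. Per the labels' protocols, RNA was extracted from 0.5 mL of blood and depleted of globin transcripts with kits made for mouse, and libraries carrying individual index tags were pooled by 13 or 14. Each pool filled 2 lanes on either of a pair of HiSeq models. The labels do not say which pool or sequencer a library belonged to, nor the sex, age or sampling date of the animals. The labels do not say whether each rodenticide-negative sample came from a different animal. Each sample was counted as 1 replicate, so p-values measure the spread between these samples. Replicate numbers follow the order of the samples and pair nothing. No 2 libraries were alike within sampling noise: the lowest chi-square between any pair was 14.7 per degree of freedom over genes with at least 20 counts in the pair, and Spearman's rho between libraries ran from 0.944 to 0.98.

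The authors deposited a table of raw counts per gene for 21887 gene IDs, which is the table used for the tests. The submitters' processing notes name Trim Galore 0.3.1, TopHat2 2.1.0 and HTSeq, and name edgeR and limma without saying for which step. The genome build, the annotation release and whether counting used strand are not given in the sources used here. The same deposited file gives a mean length and a GC fraction per gene. Many of the lengths are not whole numbers, so they are means over several features of a gene. The authors also deposited a table of normalized values on a log2 scale for 12332 of these genes. The method behind it is not stated in the labels, and the log base was read from the values: their slope on log2 counts across genes with at least 100 counts had a median of 0.97 over libraries (0.854 to 1.08). Its values run from 19 to 37.2. It holds values for 18 genes that have 0 counts in all 52 libraries of the count table. The deposited regressed table holds the same 12332 genes as log2 residuals with mean 0 per gene.

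The difference between the centred normalized values and the regressed values has rank 3, with the next singular value 2.06e-09 times the last one kept, which is what removing 3 covariate columns leaves. In the space of the libraries these columns place the animals on 3 parallel lines, which is the form of a factor with 3 levels plus 1 numeric variable that moves in equal steps. Every library lay within 0 steps (to 4 decimals) of a whole number of steps from the lowest value of its level. The levels are called A, B and C here, in order of size. What the factor and the numeric variable stand for is not stated. The scale, sign and level offsets of the numeric variable cannot be recovered. Both were used only as covariates or to split the libraries, a choice made after the tables had been seen.

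The gene IDs are Ensembl IDs with the domestic cat prefix. The gene table available here (28854 bobcat genes, assembly mLynRuf1.p) holds none of the 21887 IDs, and the deposited files do not pair IDs with names. The planned tests of functional gene lists and of blood cell type markers, the alternatives that use Y-linked genes or marker scores as covariates, and the planned look at vitamin K cycle genes were therefore not run. At most 2 IDs per direction are named: of the genes past the threshold with a mean log2 CPM of at least 1, the one with the smallest p and the one with the largest change. The planned rule for more named genes needs symbols and was not applied.

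Rodenticide-positive and rodenticide-negative libraries were compared with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr on the groups, robust dispersions, glmQLFit and glmQLFTest with rodenticide detection as the sole term, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Fold changes are rodenticide-positive over rodenticide-negative. Their standard errors were taken from the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM adds a prior count of 2. The share of variance explained by rodenticide detection is a distance-based R2 on log2 CPM with 9999 permutations of the rodenticide labels, or with all distinct splits enumerated in levels B and C. Single values per library were compared by two-sided permutation tests with 100000 resamples, or by exact enumeration in levels B and C. The expected number of genes detected at a fixed depth of 2000000 counts, computed after leaving out the 2 most abundant genes, was added after the data had been seen. Limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0 served the alternatives. Limma was run with a variance trend and robust moderation on tables of log2 values. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the rest.

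The main test was tested on simulated data: counts for 12006 genes that passed the filter, drawn from the real means, dispersions and library sizes, with 200 genes changed. It recovered 96% of genes changed 2-fold and 63% of those changed 1.5-fold, with 6 false calls among 165, and made 0 calls when nothing was changed. Each gene was drawn independently, so the simulation lacks the correlation between genes and does not measure false calls in the real libraries. Random splits of those reached 45 calls. The precision of each comparison is limited by the number of animals and by library sizes of 3405189 to 22898827 counts. The labels name no molecular identifiers on the reads, so binomial intervals cover counting error only. The subsets of level A used to judge levels B and C were 40 random draws with the number of libraries of that level, thinned to its library sizes. The design and the main alternatives for normalization, filter, test, covariates and input table were fixed before the data were examined. A naming rule was fixed then too, but the rule used for the gene IDs named here differs from it.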

Results

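Anticoagulant rodenticides are poisons that block the recycling of vitamin K, which the liver needs to make several clotting factors. Bobcats can take them up by eating poisoned prey. The study asked how the blood transcriptome of bobcats with detected rodenticides differs from that of bobcats without. Gene-level counts were compared between 26 rodenticide-positive and 26 rodenticide-negative blood samples. The tables give cat Ensembl IDs with no gene names, so the results below are given for groups of genes and for 4 gene IDs.

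Library sizes ran from 3405189 to 22898827 counts assigned to genes, with a median of 14230362. They averaged 13549328 ± 5716547 in rodenticide-positive and 12915031 ± 5052148 in rodenticide-negative samples (SD, n = 26 each), a difference smaller than the spread (permutation p = 0.672). Rodenticide-positive libraries had 14521 ± 577 genes with at least 1 count and rodenticide-negative libraries 14218 ± 509 (SD, n = 26 each; permutation p = 0.0514, adjusted p = 0.18 over 7 measures). With rodenticide labels permuted only within the 3 levels of the factor recovered from the authors' tables, the p of that difference was 0.0109. For genes with at least 10 counts the means were 11773 ± 918 and 11446 ± 771 (SD, n = 26 each; permutation p = 0.17, and 0.0521 within levels). At a fixed depth of 2000000 counts, rodenticide-positive libraries were expected to show 12957 ± 210 genes and rodenticide-negative libraries 12727 ± 302 (SD, n = 26 each; permutation p = 0.00237, adjusted p = 0.0166). This difference in gene number stood beside each gene group reported below.

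Blood libraries differed widely in 2 gene IDs that together took the largest share of counts. In rodenticide-negative samples these took 11.1% ± 11.3 of counts and in rodenticide-positive samples 6.96% ± 5.03 (SD, n = 26 each; permutation p = 0.0776, adjusted p = 0.181). The share reached 56.2% in 1 rodenticide-negative library (95% Wilson interval 56.15% to 56.2%) and was 0.563% in another (0.56% to 0.567%). Of the 52 libraries, 3 gave more than 20% of their counts to these genes.

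The levels of the factor recovered from the authors' tables differed in depth, with the lowest median in level B, and the ranges of all 3 levels overlapped. Level A held 24 libraries (13 rodenticide-positive, 11 rodenticide-negative) with a median of 15956424 counts. Level B held 17 (9 and 8) with a median of 6655434, and level C held 11 (4 and 7) with a median of 15356060. The factor accounted for 70.7% of the variance in log2 library size. A permutation version of Fisher's test of the factor against rodenticide detection gave p = 0.672, and the 3 removed covariate columns together explained 2.01% of rodenticide detection.

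**Figure D1:**
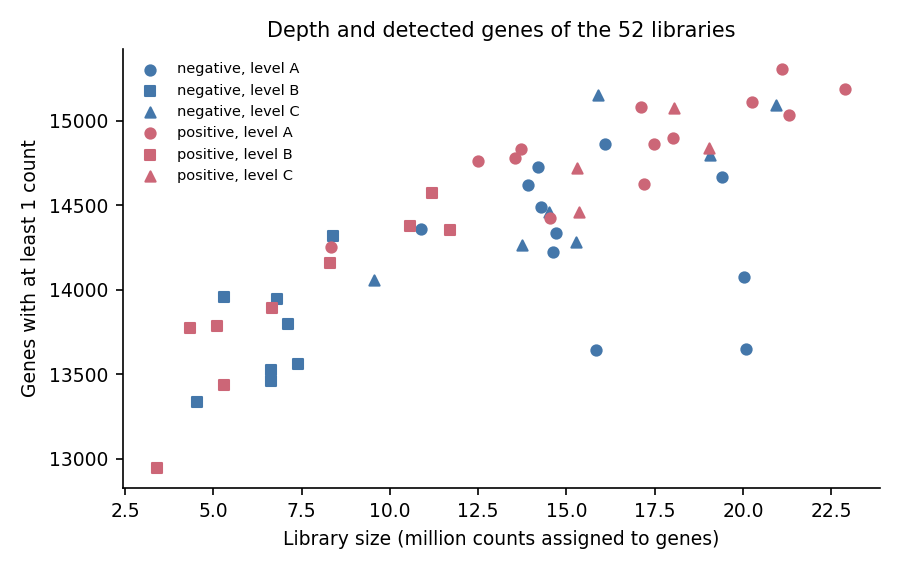
Genes with at least 1 count (vertical axis) against library size (horizontal axis, total counts) for the 52 libraries, coloured by rodenticide detection and shaped by recovered level. Level B libraries (squares) lie at the low end, with at most 11692042 counts, and 2 rodenticide-negative level A libraries of 15830862 and 20097408 counts have 13645 and 13651 genes.

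Across the whole transcriptome, rodenticide detection explained 4.7% of the variance in log2 CPM, against 1.96% on average when the rodenticide labels were permuted (permutation p = 0.003, 26 against 26 samples). Of 5 principal components tested, the first differed in mean score between the groups, although single scores overlapped widely, and it held 19.7% of the variance. Rodenticide-positive samples scored 12.3 ± 26.8 on it and rodenticide-negative samples -12.3 ± 27.7 (SD; permutation p = 0.00231, adjusted p = 0.0115 over 5 components). Components 2 to 5 gave adjusted p of 0.43 to 0.772. The score rose with the number of genes expected at the fixed depth (Pearson r = 0.898, Spearman rho = 0.902 over 52 libraries, permutation p = 1e-05 for both, the smallest the resamples can give, adjusted p = 1.5e-05 over 6 relations). Pearson's r was 0.891 without the 2 libraries farthest from the median gene number. Within level A r was 0.937 and rho 0.903 (permutation p = 1e-05 for both), within level B 0.764 and 0.787 (permutation p = 0.0002 and 0.00031), and within level C 0.939 and 0.891 (permutation p = 0.00012 and 0.00049). Within rodenticide-positive samples r was 0.882 and within rodenticide-negative samples 0.894 (permutation p = 1e-05 for both).

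The shift on the first component was largest in level A of the 3 levels. There, rodenticide-positive samples scored 26.7 ± 14.8 and rodenticide-negative samples -19.4 ± 26.7 (SD, n = 13 and 11; permutation p = 2e-05, adjusted p = 6e-05 over 3 levels). Of the 11 rodenticide-negative samples of level A, 9 scored below all 13 rodenticide-positive samples. In level B the means were -5.51 ± 31.1 and -15.1 ± 22.8 (SD, n = 9 and 8; exact permutation p = 0.482), and in level C 5.15 ± 25 and 2.21 ± 32.6 (SD, n = 4 and 7; exact permutation p = 0.861). The shift was larger by 39 in level A than in levels B and C together, where it was 7.11, and a permutation test of that difference gave p = 0.00623. rodenticide detection explained 16.3% of the variance within level A (permutation p = 0.0004), 5.23% within level B (exact permutation p = 0.659) and 6.32% within level C (exact permutation p = 0.945). The averages over the permuted labels were 4.35%, 6.25% and 10%.

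**Figure D2:**
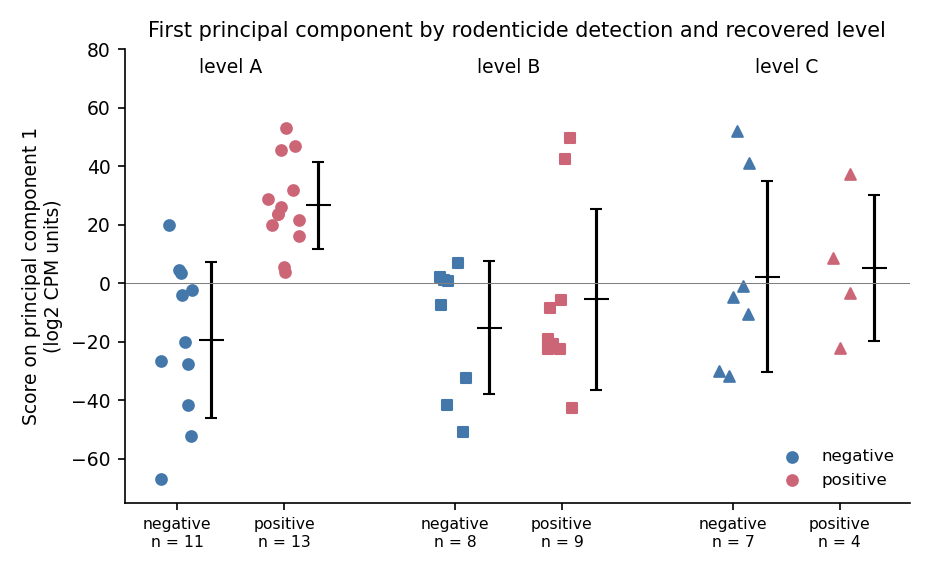
Scores on the first principal component of log2 CPM (vertical axis) for each library, by rodenticide detection within the 3 recovered levels, with the mean and SD beside each group as a bar. In level A the 13 rodenticide-positive libraries all score 3.91 or more and the 11 rodenticide-negative libraries at most 19.9, with 9 of the 11 below all 13, and the groups overlap more widely in levels B and C.

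At the level of single genes, 10 of the 12024 tested genes passed an adjusted p of 0.05 between rodenticide-positive and rodenticide-negative samples (edgeR quasi-likelihood test, Benjamini-Hochberg). In rodenticide-positive blood 7 of them were higher and 3 lower, with changes of 0.4 to 1.23 on the log2 scale. Below that threshold lay a broad set of small differences. At an adjusted p of 0.10 the test passed 457 genes, 318 higher and 139 lower. A larger number, 2639 genes (21.9%), had an unadjusted p under 0.05, where 601 would be expected by chance on average. Other random splits of the libraries had a median of 425 such genes and reached 2370. Of these 2639, 1444 were higher, with a median log2 change of 0.38, and 1195 were lower, with a median of -0.34. The median over all genes tested was -0.012.

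Among the genes at an unadjusted p under 0.05, of which 7 and 3 passed the adjusted threshold, the 1444 with higher estimates in rodenticide-positive samples had a median abundance of 8.59 CPM and a median GC content of 52.8%. The 1195 with lower estimates had 65 CPM and 48.2%, against 15 CPM and 51.5% for all genes tested. These medians across genes, which are not independent replicates, were not tested against each other.

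Among the genes past the threshold, ENSFCAG00000029870 had the smallest p. It rose from 2.06 ± 1.28 CPM in rodenticide-negative to 4.31 ± 1.61 CPM in rodenticide-positive samples (SD, n = 26 each), a log2 change of 1.05 ± 0.197 (SE; edgeR adjusted p = 0.0217), on 6 to 167 counts per library. All 26 rodenticide-positive samples lay above the rodenticide-negative median. The largest rise was that of ENSFCAG00000023786, from 8.03 ± 4.98 to 18.7 ± 20.2 CPM (SD, n = 26 each; log2 change 1.23 ± 0.274, edgeR adjusted p = 0.0485), with 23 rodenticide-positive samples above the rodenticide-negative median. Of the genes that fell, ENSFCAG00000010566 had the smallest p, at 81.2 ± 15.4 CPM in rodenticide-negative and 61.3 ± 13.6 CPM in rodenticide-positive samples (SD, n = 26 each; log2 change -0.41 ± 0.085, edgeR adjusted p = 0.043). ENSFCAG00000002680 fell most, from 10.08 ± 0.75 to 9.29 ± 0.6 log2 CPM (SD, n = 26 each; log2 change -0.85 ± 0.182, edgeR adjusted p = 0.043). In each of these 2 falling genes, 2 rodenticide-positive samples lay above the rodenticide-negative median.

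**Figure D3:**
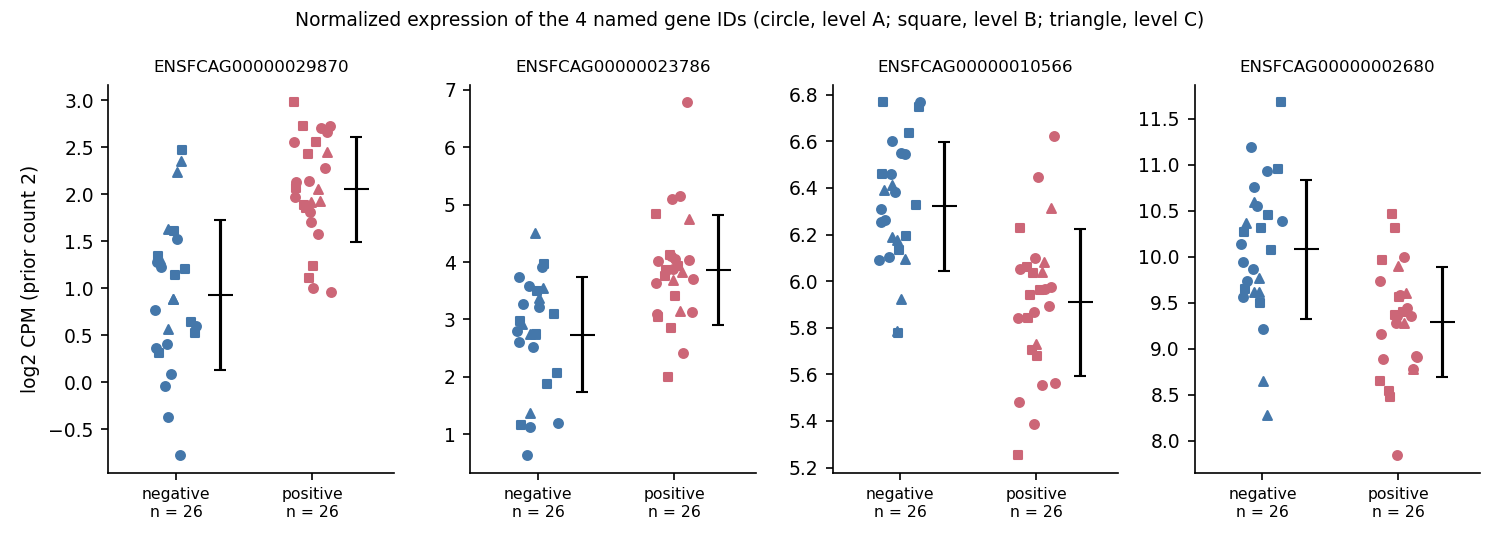
Normalized expression of the 4 named gene IDs as log2 CPM (vertical axes) in rodenticide-negative and rodenticide-positive samples, 1 point per library, shaped by recovered level, with the mean and SD of each group of 26 as a bar. ENSFCAG00000029870 and ENSFCAG00000023786 are higher and ENSFCAG00000010566 and ENSFCAG00000002680 lower in rodenticide-positive samples, with overlap between single samples.

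The estimates for all 4 genes had the same direction in each level. These genes were chosen from the test of all 52 libraries together, so a shared direction in the levels was likely. The log2 change of ENSFCAG00000029870 was 1.58 ± 0.276 in level A, 0.93 ± 0.34 in level B and 0.58 ± 0.363 in level C (SE). That of ENSFCAG00000023786 was 1.65 ± 0.45, 0.84 ± 0.378 and 0.7 ± 0.442. For ENSFCAG00000010566 the estimates were -0.46 ± 0.128, -0.54 ± 0.165 and -0.09 ± 0.171, and for ENSFCAG00000002680 -1.07 ± 0.217, -0.93 ± 0.334 and -0.28 ± 0.399. With the number of genes at the fixed depth as a covariate, the changes over 52 libraries were 0.81, 0.73, -0.33 and -0.3 in the same order, and none passed (edgeR adjusted p = 0.27 for ENSFCAG00000029870 and 1 for the others). Over 76 alternatives the adjusted p ran from 0.00052 to 1 for ENSFCAG00000029870, from 0.00636 to 1 for ENSFCAG00000023786, from 0.00364 to 1 for ENSFCAG00000010566 and from 0.00294 to 1 for ENSFCAG00000002680.

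Within level A alone, 3008 of 12167 genes passed an adjusted p of 0.05, 1625 higher and 1383 lower in rodenticide-positive samples (edgeR). With the number of genes at the fixed depth as a covariate, 0 passed in level A (edgeR; 1079 at an unadjusted p under 0.05), and the log2 changes of the 3008 genes had a median of 0.409 times their former size. In level B 0 of 10883 genes passed and in level C 0 of 12370 (edgeR), with 2.22% and 1.21% at an unadjusted p under 0.05, against 38.6% in level A. The shares in levels B and C lie below the 0.05 expected on average with no change. Such counts vary widely: with shuffled rodenticide labels, level A had between 100 and 3444 genes. No other tool was run within levels. Of the 3008 genes, 2906 were also tested in levels B and C together, and 73.8% of those had an estimate in the same direction there. The higher ones had a median log2 change of 0.63 in level A and 0.11 in levels B and C, and the lower ones -0.58 and -0.06. Because these genes were chosen for passing in level A, their level A medians are inflated and a drop elsewhere would be seen even with equal effects. Over all genes tested in both, chosen by no result, the log2 changes of level A and of levels B and C correlated with r = 0.29 across genes. Gene by gene, a test of the interaction between rodenticide detection and level passed 1 gene at an adjusted p of 0.05 and 956 at an unadjusted p under 0.05 (edgeR). Level A against the other levels, with the recovered covariates, passed 0 genes at an adjusted p of 0.05 and 1795 at an unadjusted p under 0.05 (edgeR, the sole tool run for it). The number of genes expected at the fixed depth differed along with these groups: in level A it was 13086 ± 114 in rodenticide-positive and 12670 ± 337 in rodenticide-negative samples (SD, n = 13 and 11; permutation p = 0.00014). The mean was 112 higher in rodenticide-positive samples in level B (n = 9 and 8; exact permutation p = 0.289) and 35.9 higher in level C (n = 4 and 7; exact permutation p = 0.836).

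The authors' own tables gave more genes past an adjusted p of 0.05. Limma passed 152 of 12332 genes in the normalized table, 124 higher and 28 lower, and 605 in the regressed table, 486 higher and 119 lower. At an unadjusted p under 0.05 these tables had 2605 and 3136 genes, against 2639 from the counts in edgeR. Of the 10 genes from the counts, 8 passed in the normalized and 9 in the regressed table, each in the same direction, where independent lists would share 0.1 and 0.5. Log2 changes from the counts and from the regressed table correlated across 11949 genes (r = 0.879) and had the same sign in 84% of them. Genes are not independent replicates, and both tables come from the same libraries. With the recovered factor and numeric variable as covariates, the count test passed 15 genes, 8 of them among the 10, and 3104 at an unadjusted p under 0.05.

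The number of genes past the threshold depended on single libraries, the test, the normalization, the filter and the covariates. Leaving out 1 library at a time gave between 0 genes (without rodenticide-positive replicate 26) and 645 genes (without rodenticide-negative replicate 20), and DESeq2 and limma voom with quality weights passed 305 and 1633 genes. It was 1 with upper-quartile factors, with no filter or with the title number as covariate, and 0 with surrogate variables (777 at an unadjusted p under 0.05) or the first principal component (458) as covariates, all in edgeR. The count at an unadjusted p under 0.05 stayed between 2289 and 3278 over the same omissions.

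**Figure D4:**
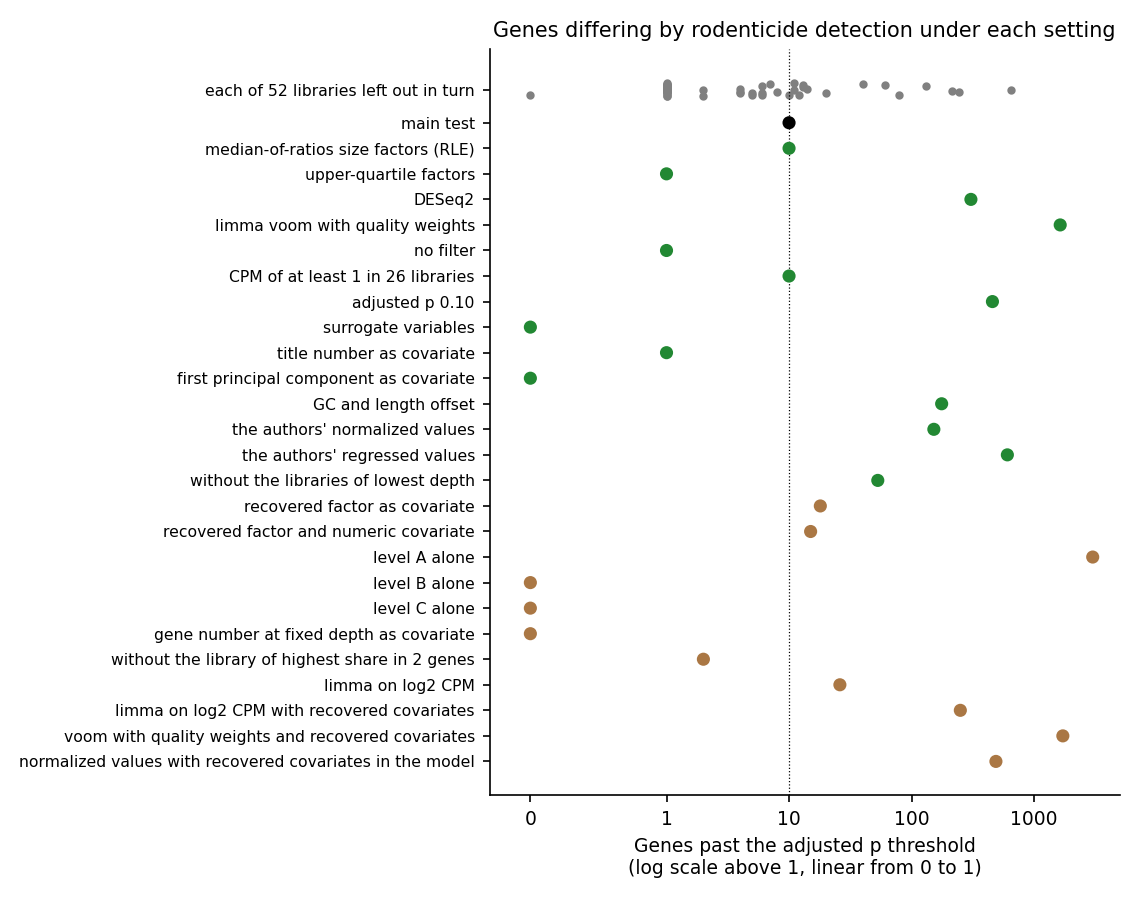
Number of genes past the adjusted p threshold between rodenticide-positive and rodenticide-negative samples (horizontal axis, log scale above 1) under each setting named on the vertical axis. The main test is black at 10 genes, alternatives set at the outset are green, those added after seeing the data brown, and the 52 single-library omissions grey, spanning 0 to 645 genes.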

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

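The split by level, every test of it and the comparison of unadjusted counts with subsets of level A were chosen after the data had been examined. On the first principal component, the shift with rodenticide detection differed between the levels of the factor recovered from the authors' tables: it was larger by 39 in level A than in levels B and C, with a permutation p of 0.00623 for the difference. Gene by gene the evidence was thin: the interaction of rodenticide detection with level passed 1 gene in edgeR, and level A against the other levels, with the recovered covariates, passed 0 (1795 at an unadjusted p under 0.05). Level A alone gave 3008 genes past an adjusted p of 0.05. Of 100 splits of its 24 libraries 1, the real one, reached that number, and the highest of the others was 718, so chance can be excluded at the 0.05 level within level A taken by itself. The splits leave out the choice of level A among 3 levels, which was made after the data had been examined. Omitting 1 library of level A left between 2283 genes (without rodenticide-negative replicate 13) and 3664 genes (without rodenticide-negative replicate 6).

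In the range of title numbers shared by both rodenticide groups of level A (12 rodenticide-positive and 5 rodenticide-negative libraries) 200 genes passed, 197 of them among the 3008. These libraries are part of level A, so a large overlap was likely. The other rodenticide-negative libraries of level A had title numbers below those of all its rodenticide-positive ones. No subsets of level A of that size were drawn for comparison, so whether blocks of title numbers account for the other calls stays open. With the title number as a linear covariate, level A passed 2145 genes (edgeR), which covers a straight trend and not blocks. Random subsets of level A with the library number and depth of level B called a median of 797 genes (0 to 2686, with 10 or fewer in 5 of 40 draws), and those matched to level C a median of 0 (0 to 1045), so the counts past the threshold do not separate the levels by themselves. At an unadjusted p under 0.05, however, the subsets had at least 1968 and 895 genes in 40 draws each, while level B had 2.22% of 10883 genes and level C 150 genes, which argues against fewer libraries and lower depth as the whole reason, although subsets of 1 level overlap and vary less than separate samples would. Library complexity is a candidate explanation: with the number of genes expected at a fixed depth as a covariate, level A passed 0 genes in edgeR (1079 at an unadjusted p under 0.05), and the log2 changes of the 3008 genes shrank to a median of 0.409 times their size. That number is read from the same transcriptome and would also move with the genes active in the blood of rodenticide-positive animals, so RNA quality, cell composition, which was not tested for want of gene names, and an effect of rodenticides stay open.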

How the results depend on the processing

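The alternatives that used the recovered covariates, single levels, single-library omissions, the number of genes at a fixed depth, limma on log2 CPM and the omission of the library with the highest share in 2 genes were added after the data had been seen. From 10 genes in the main edgeR test, the count stayed at 10 with median-of-ratios size factors and with a CPM of at least 1 in 26 libraries, and was 15 with the recovered factor and numeric covariate. It was 1 with upper-quartile factors, with no filter (18304 genes tested) and with the title number as covariate, and in each case the gene was higher. It was 0 with 9 surrogate variables (777 genes at an unadjusted p under 0.05), 0 with the first principal component (458) and 0 with the number of genes at a fixed depth (368) as covariates. It was 2 without the library with 56.2% of its counts in 2 genes, 18 with the recovered factor alone, 26 with limma on log2 CPM, 53 without the 3 libraries of lowest depth, 152 in the authors' normalized table, 176 with a GC and length offset, 250 with limma on log2 CPM and the recovered covariates, 305 with DESeq2, 457 at an adjusted p of 0.10, 488 in the normalized table with the covariates in the model, 605 in the regressed table, 1633 with limma voom and quality weights, and 1716 with these and the covariates. It was 3008 in level A, 0 in level B and 0 in level C. Single-library omissions gave 0 to 645 genes. Of the 52 omissions 43 moved the count by over 1.5 times, 35 to fewer and 8 to more. It was 0 without rodenticide-positive replicate 26 (edgeR; 2332 genes at an unadjusted p under 0.05), and 1 without rodenticide-negative replicate 1, 2, 3, 6, 7, 8, 12, 13, 16, 18, 23 or 25 or positive replicate 1, 4, 6, 9, 10, 12, 14, 15, 16, 18, 20 or 25. It was 2 to 6 without negative replicate 5, 9, 19, 21 or 22 or positive replicate 7, 13, 17, 19 or 23. It was 20 without negative replicate 24, 40 without negative 11, 61 without negative 26, 79 without positive 2, 130 without positive 22, 213 without positive 3, between that and 645 without negative 17, and 645 without negative 20. ENSFCAG00000029870 passed in 70 of 76 alternatives and the other 3 named genes in 30 (ENSFCAG00000023786), 38 (ENSFCAG00000010566) and 39 (ENSFCAG00000002680), and none of the 4 changed direction. Of the 76, 52 are single-library omissions that share all but 1 library with the main test, so the alternatives are not independent of it. ENSFCAG00000029870 did not pass with surrogate variables (log2 change 0.7, edgeR adjusted p = 0.556), the first component (0.77, 0.386) or the gene number (0.81, 0.27) as covariates, in level B (0.93, 0.992) or C (0.58, 1), or without positive replicate 26 (1, 0.051).

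The variance share of 4.7% was 5.16% in the regressed and 4.47% in the normalized table, 4.46% on z scores, 5.45% with the recovered covariates removed and 16.3% in level A, all past the threshold. It was 5.23% in level B and 6.32% in level C, not past it. The difference of 303 genes with at least 1 count passed when labels were permuted within levels (permutation p = 0.0109), and that of 327 genes with at least 10 counts did not pass (permutation p = 0.17, and 0.0521 within levels). The cause of these changes was not tested, except as weighed for level A, for the title number and for the authors' tables. All tests of gene lists and markers, and the covariates built from them, were not run for want of gene names.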

Other observations

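The fits of the authors' tables and the fit with the title number were set at the outset, but the fits of limma on log2 CPM, the fits with recovered covariates and the ratios that weigh the explanations below were chosen after the results were seen.

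Random splits of the 52 libraries into 2 groups of 26 show how much weight each count carries. In 3 of 100 splits, the real one included, 10 or more genes passed an adjusted p of 0.05 in the main test, with 45 as the highest of the others. For the 2639 genes at an unadjusted p under 0.05 the real split alone, 1 of 100, reached that number, with 2370 as the highest of the others and a median of 425. For the 152 genes of the normalized values it was 1 of 100, with 2 as the highest of the others, and for the 605 genes of the regressed values it was 1 of 100, with 1 as the highest of the others. Chance can be excluded at the 0.05 level for the counts of 2639, 152 and 605. For the count of 10 the share of splits is under 0.05 too, but with 2 of the 99 other splits above it and a result that rests on single libraries, chance is not firmly excluded: 24 of the 52 single-library omissions left 1 gene and 1 left 0 (edgeR; without rodenticide-positive replicate 26, 2332 at an unadjusted p under 0.05), and 8 of the 100 splits reached 1 gene or more, so at a count of 1 chance is not excluded. What the split with 45 genes, several times the real count, follows among the libraries was not examined, and correlation between genes also gives such counts.

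The authors' regressed table gave 605 genes and the counts 10. The covariates and the normalization may account for this in part. With limma on log2 CPM, adding the recovered covariates multiplied the calls by 9.62 (26 to 250), although in edgeR the same covariates moved 10 genes to 15. With limma and no covariates, the normalized table gave 5.85 times the calls of log2 CPM (152 against 26). Degrees of freedom not reduced for the removed covariates are argued against as the whole reason, since the regressed table gave 1.24 times the 488 calls of the normalized table with the covariates in the model. Which of the 2 sets is nearer the true number of changed genes stays open.

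The number in the sample titles was on average 4.92 higher in rodenticide-positive than in rodenticide-negative samples (SD 23.3 and 30.2, n = 26 each; permutation p = 0.516). In a model with rodenticide detection, 246 genes had a slope on the title number at an adjusted p of 0.05 (edgeR). With it as a covariate 1 gene passed for rodenticide detection in place of 10, because adjusted p values just under the threshold moved just over it: ENSFCAG00000010566 went from -0.41 (adjusted p = 0.043) to -0.39 (0.0675) on the log2 scale, within a range of adjusted p from 0.00364 to 1 over its alternatives. The log2 changes of the 10 genes had a median of 0.971 times their former size, which argues against a trend with title number as the reason for their differences. What the title number records is not stated in the labels.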
